A study of Homo sapiens with 14 samples.

How the data were processed

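RNA-seq was done on 14 libraries of MOLM14, a human acute myeloid leukaemia cell line. Per the labels' protocols, the early resistant lines were grown with FGF2 or with FLT3 ligand (FL) at 10 ng/mL, and the early and acute cultures received gilteritinib at 100 nM for 48 hours. Stranded poly(A) libraries were made with a TruSeq mRNA kit and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. Reads were quantified with kallisto, and GRCh37 is given as the genome build, per the submitters' processing notes, which name no kallisto version.

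The deposited table holds estimated counts per Ensembl gene and library, not normalized for depth, since the column totals run from 25723575 to 33075041. It has 39293 gene identifiers, and 0.054% of its values above 0 are whole numbers within 1e-06, as estimated counts shared between transcripts would give. How the authors summed transcripts to genes, and whether they rescaled the counts by transcript length, is not stated. The reference at hand was GENCODE 29 for another build, so it served only for names and transcript lengths, and no coordinates are given. A gene name was found for 28953 identifiers (73.7%), and the others held 4.32% to 5.13% of the counts of a library. Members of near-identical families (HSPA7, FCGR2C, RIMBP3C and the histone genes), and LSP1, carry uncertain values, because reads can be assigned to the wrong copy. Reads of HLA genes can also go to identifiers of alternative sequences. Y-linked genes and XIST were left out of the named genes.

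Counts were rounded to whole numbers, genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), and 15756 genes were tested. The 14 libraries were fitted together in 4 arms with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood test), with Benjamini-Hochberg adjustment at 0.05. The arms were FGF2 early (4 libraries), FL early (4), untreated parental (3) and acute (3). The acute arm holds 1 library each of parental cells given gilteritinib alone, with FGF2 and with FL, so its spread includes the differences between ligands. Early against a control means the average of the FGF2 early and FL early arms minus that control. Adjusted p-values for genes are from this edgeR test. Expression is given in CPM, counts scaled to a common depth, computed with TMM library sizes, as mean ± SD over libraries, and log2 fold changes are given ± standard error. The eosinophil markers near the end were instead scaled to total counts alone. Nothing states that the parental libraries came from separate cultures, or that the flasks of an early line were derived independently. If they were not, p-values measure only the spread between these samples. For genes with at least 50 counts over a pair of libraries, counting error was on average small beside the spread between libraries of an arm. Genes with fewer counts were left out of that check. The first dispersion value held by the edgeR fit corresponded to a biological coefficient of variation of 0.132.

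Before the data were examined, the comparisons, 37 gene lists, a panel of 26 genes and the rule for named genes were fixed. The rule passes over withheld genes, which left 25 of the panel. It names the panel, the 8 genes with the largest change in each direction (5 for acute vs parental and for FGF2 early vs FL early) and up to 4 members of a described list with the smallest adjusted p. Genes with the largest change needed an adjusted p under 0.05, a mean log2 CPM of at least 3 and complete separation of the libraries compared. Lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, a two-sided test and adjustment over the 37 lists of a comparison. Camera was also run with an estimated correlation, and fry tested whether the members of a list moved on balance in 1 direction. Counts of list members are given adjusted over all genes tested and adjusted over the list alone. With 1 library per ligand state there was no test within the acute arm, and list medians there were placed among 10000 random lists matched on expression. Principal components were computed on log2 CPM of the tested genes, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

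The scripts were tested on simulated counts with known changes, in 66 or 67 genes for each fold. For early vs parental (14950 genes) they recovered 34.3% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 89.4% of those changed 4-fold, and 6.57% of the calls were false. For early vs acute (15290 genes) the shares were 44.8%, 77.6% and 80.3%, and 4.93% of the calls were false. Far fewer genes changed in the simulated counts than were called in the data, so these shares need not hold for the data. The alternatives changed the scaling, the filter, the test (DESeq2 1.42.0, limma-voom, fry), the correlation, the fold threshold, the make-up of the acute arm and the libraries in the fit, and left out each library in turn. Alternatives added after the data were seen left out FL early replicates 1 and 4 together, used only identifiers with a name, or scaled without ribosomal protein and mitochondrial genes. Alternatives that need TPM, transcript values or lengths from the deposited file were not run, because it holds none.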

Results

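Gene expression was measured in MOLM14 cells, an acute myeloid leukaemia line with an internal tandem duplication in FLT3, during resistance to gilteritinib, an inhibitor of the FLT3 and AXL kinases. There were 14 libraries with total counts between 25723575 and 33075041. Early resistant cells came from 4 flasks kept with FGF2 and 4 flasks kept with FL, the ligand of FLT3. Controls were 3 libraries of untreated parental cells and 3 of acutely treated parental cells, 1 each with gilteritinib alone, with FGF2 and with FL.

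The acute libraries stood apart from all others. On the first principal component, which held 47.3% of the variance, they lay between 104.6 and 122.6, and the other libraries between −48.6 and −5.66. The second component (19.2%) separated FGF2 early flasks (45.7 to 49.4) from parental libraries (−55.3 to −51.0). FL early replicates 1 to 4 lay between these at −9.02, −34.8, −33.7 and 16.9. The third component (9.47%) separated FL early flasks (−47.5 to −22.6) from parental libraries (29.4 to 35.7). Correlations of log2 CPM across genes between libraries of an arm were 0.985 to 0.988 for FGF2 early, 0.969 to 0.985 for FL early, 0.985 to 0.988 for parental and 0.975 to 0.984 for acute. These are across genes, which are not independent replicates. Ribosomal protein transcripts took 16.3% to 19.7% of counts in acute libraries and 10.8% to 13.0% in the others. Transcripts encoded in mitochondrial DNA took 3.52% to 3.91% in acute libraries and 4.26% to 5.31% in the others.

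**Figure D1:**
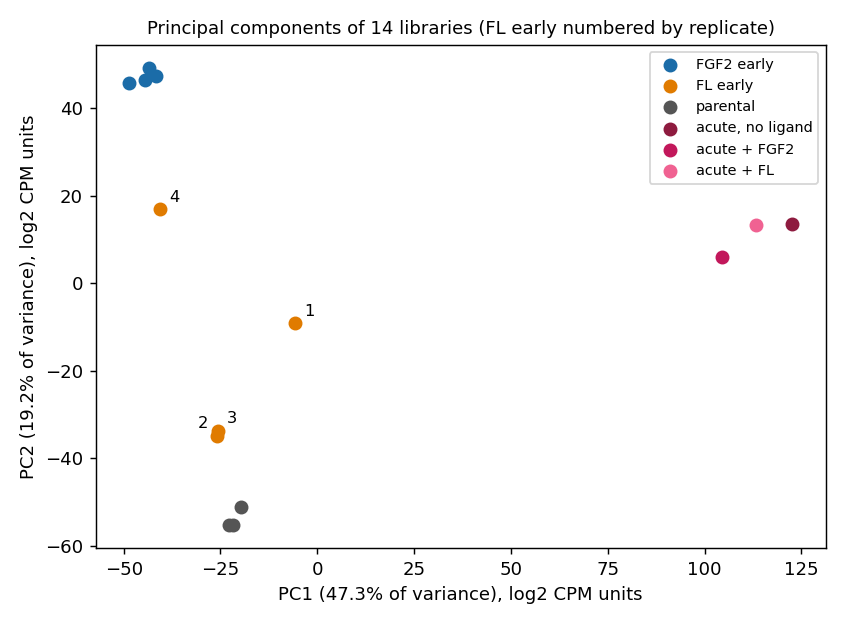
Principal components of log2 CPM for the 14 libraries, coloured by group, with PC1 (47.3% of variance) on the horizontal and PC2 (19.2%) on the vertical axis, in log2 CPM units. The 3 acute libraries lie above 100 on PC1, and the numbered FL early replicates spread on PC2 from −34.8 to 16.9.

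Early resistant cells were compared with untreated parental cells to find what differed once cells grew in the inhibitor with a ligand. Granule genes of the neutrophil lineage rose on average over both lines. Of 15 targets of STAT5, a transcription factor activated by FLT3 with the tandem duplication, 7 fell and 2 rose, and the call of that list was lost with an estimated correlation (adjusted p = 0.379). PRTN3 (ENSG00000196415), the gene of proteinase 3, rose from 161 ± 41.5 CPM (SD, n = 3) to 1022 ± 516 CPM (n = 8), a log2 fold change of 2.54 ± 0.26. PIM1 (ENSG00000137193), a survival kinase and STAT5 target, fell from 49.0 ± 1.30 CPM to 3.80 ± 2.66 CPM, a log2 fold change of −3.91 ± 0.22. AXL (ENSG00000167601), a receptor kinase linked to escape from FLT3 inhibitors, rose from 7.50 ± 0.73 CPM to 21.2 ± 8.58 CPM (1.42 ± 0.25, adjusted p = 0.0011), though FL early replicates 2 and 3, at 8.89 and 8.65 CPM, lay close to the parental libraries (6.91 to 8.31 CPM). FLT3 itself (ENSG00000122025) stood at 401 ± 53.4 CPM in early and 377 ± 11.4 CPM in parental cells (0.08 ± 0.08, adjusted p = 0.490). Of 15756 genes, 2160 were higher and 2540 lower in early cells, of which 389 and 683 changed at least 2-fold.

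Of 14 granulocyte differentiation genes, 12 rose and none fell, with the same counts adjusted over the list alone. The median was 1.65 and camera gave an adjusted p of 1.09e-05, with adjusted p = 0.0433 with an estimated correlation. These counts are for the average of both lines, and some of the rises came from FL flasks alone. MPO was lower in every FGF2 early flask (32.3 to 46.1 CPM) than in the parental libraries (60.6 to 79.2 CPM). EPX stood at 2.30 to 5.94 CPM with FGF2 and at 1.49 CPM in FL early replicate 1, against 2.48 to 2.86 CPM in parental libraries. CTSG and AZU1, which encode the granule proteins cathepsin G and azurocidin, rose by 1.83 ± 0.16 and 1.65 ± 0.17, and ELANE, the neutrophil elastase gene, by 2.13 ± 0.26. Of 10 MHC class II genes, which serve antigen presentation to helper T cells, 7 fell and 1 rose (8 and 1 adjusted over the list alone). Their median was −1.27, with an adjusted p of 1.73e-04 by camera and adjusted p = 0.0433 with an estimated correlation. CD74, the invariant chain, had a change of −0.91 ± 0.07, and CIITA, the master activator of these genes, one of −1.08 ± 0.11.

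Among 15 STAT5 targets, 7 fell and 2 rose (7 and 3 adjusted over the list alone), with a median of −0.28. Camera gave an adjusted p of 0.0025, and adjusted p = 0.379 with an estimated correlation. CISH, a feedback inhibitor of cytokine signalling, fell from 44.8 ± 3.20 CPM to 11.6 ± 1.15 CPM (−1.96 ± 0.09), and SOCS1 and SOCS3, inhibitors of the same kind, changed by −2.27 ± 0.22 and −2.38 ± 0.27. Of 22 genes induced by RAS-MAPK signalling, 6 fell and 2 rose (6 and 3 adjusted over the list alone), and the list did not pass with camera (median −0.26, adjusted p = 0.175). Fry called it lower (adjusted p = 0.0297). EGR3 and DUSP4, both early targets of ERK, changed by −2.90 ± 0.27 and −2.50 ± 0.33 from low parental levels (3.40 to 5.07 and 5.94 to 6.24 CPM). More abundant members were divided. EGR1 stood at 92.2 to 109 CPM with FGF2 and 13.4 to 24.7 CPM with FL, below the parental libraries (135 to 155 CPM). FOSL1 was also lower, at 12.1 to 14.8 CPM in early against 16.8 to 17.9 CPM in parental libraries. FOS and DUSP6 did not follow them. FOS stood at 215 to 249 CPM with FGF2 and 59.7 to 127 CPM with FL, against 74.5 to 77.9 CPM in parental libraries. DUSP6 stood at 94.0 to 107 CPM with FGF2 and 50.2 to 109 CPM with FL, against 63.3 to 69.8 CPM. FOXO targets, induced when PI3K signalling is low, did not pass with camera either (median 0.39, adjusted p = 0.0580), with 9 of 19 higher and 2 lower, also when adjusted over the list alone. Fry called them higher (adjusted p = 0.0133).

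Cell cycle genes fell by a small amount. In the G2-M and mitosis list 24 of 39 genes fell and none rose (28 adjusted over the list alone), with a median of −0.36 and an adjusted p of 1.39e-09, but adjusted p = 0.528 with an estimated correlation. CDK1, the kinase that drives entry into mitosis, fell from 163 ± 11 CPM to 101 ± 13.4 CPM (−0.69 ± 0.08), and KIF11, a spindle motor, changed by −0.56 ± 0.07. In the G1-S and DNA replication list 21 of 37 fell and 1 rose (25 and 1 adjusted over the list alone), with a median of −0.30 and an adjusted p of 3.34e-08, but adjusted p = 0.379 with an estimated correlation. RFC3 and FEN1, both DNA replication factors, changed by −0.60 ± 0.05 and −0.42 ± 0.06. Of 13 Aurora kinase and chromosomal passenger genes, 7 fell and none rose (8 adjusted over the list alone), with a median of −0.26 and an adjusted p of 0.0036, but adjusted p = 0.528 with an estimated correlation. AURKA, a mitotic kinase, changed by −0.51 ± 0.10 and its activator TPX2 by −0.36 ± 0.06.

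Some growth and metabolic lists were also lower, and others did not pass. MYC targets and ribosome biogenesis genes fell in 12 of 33 cases and rose in none (14 adjusted over the list alone; median −0.25, adjusted p = 1.68e-04, but adjusted p = 0.699 with an estimated correlation). ODC1, the first enzyme of polyamine synthesis, changed by −0.38 ± 0.07, and fry did not call this list (adjusted p = 0.0548). Cytosolic ribosomal protein genes fell in 12 of 42 cases and rose in 1, also adjusted over the list alone (median −0.20, adjusted p = 3.55e-04, but adjusted p = 0.812 with an estimated correlation and 0.120 with fry). Respiratory chain genes of the nucleus fell in 14 of 36 cases and rose in 1 (16 and 1 adjusted over the list alone), with a median of −0.19 and an adjusted p of 1.68e-04, but adjusted p = 0.528 with an estimated correlation. NDUFA1 and COX6C, subunits of complexes of that chain, changed by −0.40 ± 0.06 and −0.41 ± 0.07. ATF4 targets, which serve amino acid supply, fell in 14 of 32 cases and rose in 3 (16 and 3 adjusted over the list alone), with a median of −0.29 and an adjusted p of 3.51e-04, but adjusted p = 0.528 with an estimated correlation. MTHFD2, an enzyme of mitochondrial folate metabolism, changed by −0.50 ± 0.06 and SARS1, the seryl-tRNA synthetase, by −0.47 ± 0.05. Glycolysis (3 higher and 6 lower of 24, 3 and 8 adjusted over the list alone; adjusted p = 0.180) and mitochondrially encoded genes (1 and 1 of 13, 0 and 1 adjusted over the list alone; adjusted p = 0.493) did not pass.

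Interferon-stimulated genes rose in 14 of 31 cases and fell in 3 (17 and 3 adjusted over the list alone), with a median of 0.49 and an adjusted p of 0.0011, but adjusted p = 0.528 with an estimated correlation. IFIT3 rose from 0.353 ± 0.165 CPM to 3.04 ± 1.16 CPM (3.02 ± 0.37), and OAS3, a sensor of double-stranded RNA, by 1.76 ± 0.27. Targets of p53 rose in 7 of 25 cases and fell in 2 (9 and 2 adjusted over the list alone), with a median of 0.20 and an adjusted p of 0.0200, but adjusted p = 0.528 with an estimated correlation. FAS, a death receptor, rose by 0.67 ± 0.10 and BTG2, an antiproliferative gene, fell by 1.28 ± 0.15 on the log2 scale. Lipid lists did not pass: cholesterol synthesis (1 higher and 2 lower of 24; adjusted p = 0.888), fatty acid synthesis (1 and 2 of 19; 0.888) and fatty acid oxidation and uptake (5 and 4 of 29; 0.890). Adjusted over the list alone, these counts were 0 and 1, 1 and 2, and 5 and 5. In the oxidation list CPT1A, which carries fatty acids into mitochondria, rose from 92.8 ± 3.68 CPM to 142 ± 13.0 CPM (0.61 ± 0.10), and CD36, a fatty acid transporter, fell from 6.40 ± 0.28 CPM to 1.90 ± 0.39 CPM (−1.75 ± 0.22). The adhesion and migration list changed in both directions (13 higher and 8 lower of 23, 13 and 10 adjusted over the list alone), with adjusted p = 0.888 by camera. Fry called it lower (adjusted p = 0.0102). The chemokine receptor CCR1 in it fell from 43.0 ± 0.85 CPM to 6.15 ± 1.35 CPM.

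The largest rises among separated genes were in EVPL (2.62 ± 0.51), TMTC2 (2.59 ± 0.34), CFD (2.56 ± 0.59), PRTN3, the testis and myeloid cyclin gene CCNA1 (2.19 ± 0.36), CEBPD (2.17 ± 0.32), HOMER3 (2.15 ± 0.15) and ELANE. The largest falls were in PIM1, IGFBP2 (−3.85 ± 0.25), ALDH1A3 (−3.77 ± 0.31), NRP1 (−3.67 ± 0.20), the chemokine receptor genes CCR2 (−3.07 ± 0.28) and CCR1 (−2.81 ± 0.13), SLC44A1 (−2.75 ± 0.20) and EPHB3 (−2.51 ± 0.18). In the panel NRAS changed by −0.31 ± 0.06 (adjusted p = 0.0012). MYC stood at 602 ± 58.7 CPM in early and 611 ± 47.1 CPM in parental cells (−0.02 ± 0.26, adjusted p = 0.957; 0.04 without parental replicate 3). CDKN1A, a cell cycle inhibitor, changed by 0.53 ± 0.19 (adjusted p = 0.0532), and without FL early replicate 1 by 0.65 (adjusted p = 5.26e-05). AURKB passed at −0.33 ± 0.09, but not without parental replicate 1 or 3 (adjusted p = 0.0528 and 0.0557), and BCL2 at −0.28 ± 0.08, but not without parental replicate 1 or 2 (0.121 and 0.0734). MKI67 passed at −0.39 ± 0.13, but not without FGF2 early replicate 1 or 2, FL early replicates 1 and 4 together or any parental library (adjusted p = 0.0544 to 0.0985). BCL2L11 passed at 0.20 ± 0.07, but not with RLE size factors (adjusted p = 0.0585), upper quartile scaling (0.0644), limma-voom (0.0526), no low-count filter (0.0773), only named identifiers (0.0627) or scaling without ribosomal protein and mitochondrial genes (0.0694). Nor did it pass without FGF2 early replicate 3 or 4, FL early replicate 2 or 3 or any parental library (adjusted p = 0.0557 to 0.152). Without parental replicate 1, 1163 genes were higher and 1621 lower, without parental replicate 2, 1136 and 1549, and without parental replicate 3, 1771 and 1980.

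**Figure D2:**
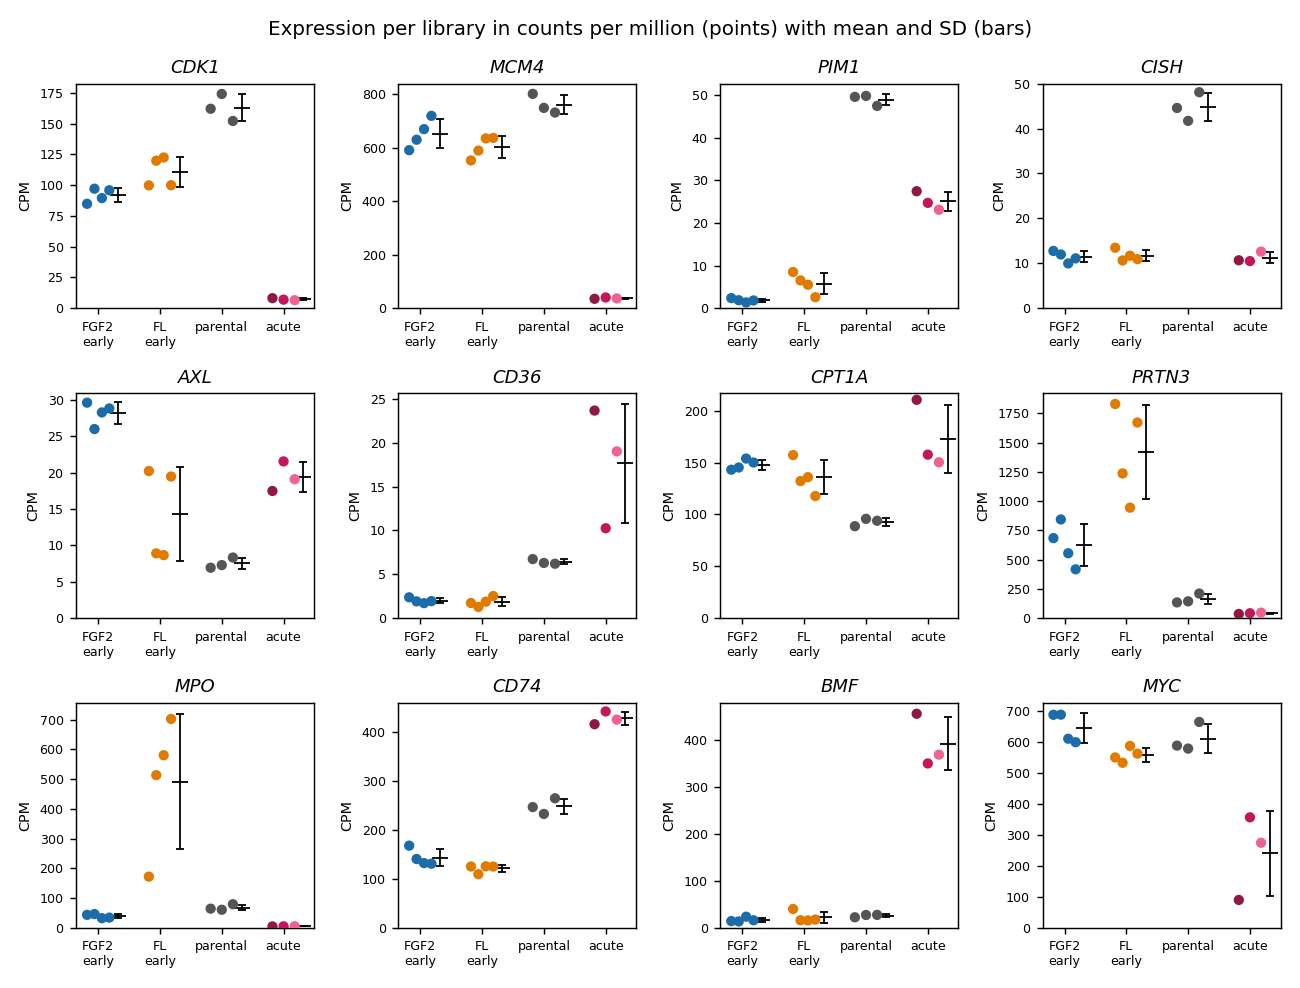
Expression (CPM) of 12 named genes in each of the 14 libraries, by arm (4 FGF2 early, 4 FL early, 3 parental, 3 acute in shades of red for no ligand, FGF2 and FL). Points are libraries and black bars the mean and SD, with PIM1 at 49.0 ± 1.30 CPM in parental and 3.80 ± 2.66 CPM over the early libraries.

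Early resistant cells were compared with acutely treated cells to separate established growth in the inhibitor from the first response to it. Every gene tested of the replication and mitosis lists was higher in early cells. CDC6 (ENSG00000094804), which loads the replicative helicase, stood at 72.6 ± 7.24 CPM (n = 8) in early and 1.77 ± 0.39 CPM (n = 3) in acute cells, a log2 fold change of 5.34 ± 0.13. BMF (ENSG00000104081), a pro-apoptotic BH3-only gene, stood at 19.5 ± 8.79 CPM in early and 391 ± 56.4 CPM in acute cells, a change of −4.34 ± 0.24. MYC was higher at 602 ± 58.7 CPM against 240 ± 137 CPM (1.32 ± 0.28, adjusted p = 8.77e-04), and by 2.77 when only the acute library without ligand was used. AXL did not differ detectably (0.05 ± 0.23, adjusted p = 0.855), and without FL early replicates 1 and 4, an alternative added later, it was lower (−0.24, adjusted p = 0.0315). In all, 5056 genes were higher and 5342 lower, of which 1888 and 2526 changed at least 2-fold.

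All 37 G1-S and DNA replication genes rose, also adjusted over the list alone (median 3.39, adjusted p = 7.12e-22, and adjusted p = 0.0428 with an estimated correlation). MCM4, a helicase subunit, rose by 4.09 ± 0.09. All 39 G2-M and mitosis genes rose, also adjusted over the list alone (median 3.18, adjusted p = 7.12e-22, but adjusted p = 0.141 with an estimated correlation), with CDK1 up by 3.81 ± 0.11 and CCNA2, its cyclin partner, by 4.12 ± 0.12. Aurora kinase and passenger genes rose in 11 of 13 cases and fell in 1, also adjusted over the list alone (median 2.90, adjusted p = 1.95e-06, but adjusted p = 0.173 with an estimated correlation), AURKB by 3.28 ± 0.12. MYC targets and ribosome biogenesis genes rose in 32 of 33 cases, also adjusted over the list alone (median 1.17, adjusted p = 2.65e-11, but adjusted p = 0.264 with an estimated correlation). Polyadenylated histone transcripts fell in all 9 genes tested, also adjusted over the list alone (median −2.98, adjusted p = 1.47e-04, but adjusted p = 0.0861 with an estimated correlation). Ribosomal protein genes fell in 37 of 42 cases and rose in none, also adjusted over the list alone (median −0.67, adjusted p = 1.65e-08, but adjusted p = 0.399 with an estimated correlation).

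Several biosynthetic and energy lists were higher in early cells. ATF4 targets rose in 24 of 32 cases and fell in 5, also adjusted over the list alone (median 0.95, adjusted p = 9.69e-06, but adjusted p = 0.239 with an estimated correlation). PSAT1 and PHGDH, enzymes of serine synthesis, rose by 3.16 ± 0.12 and 3.17 ± 0.13. Glycolysis genes rose in 17 of 24 cases and fell in 2, also adjusted over the list alone (median 0.84, adjusted p = 2.71e-04, but adjusted p = 0.392 with an estimated correlation), LDHA by 2.56 ± 0.15. Fatty acid synthesis genes rose in 15 of 19 cases and fell in 2 (16 and 2 adjusted over the list alone; median 0.93, adjusted p = 8.50e-04, but adjusted p = 0.239 with an estimated correlation). SCD, the stearoyl-CoA desaturase, rose from 119 ± 26.1 CPM to 828 ± 216 CPM (2.79 ± 0.28). Nuclear respiratory chain genes rose in 25 of 36 cases and fell in 2, also adjusted over the list alone (median 0.51, adjusted p = 8.70e-06, but adjusted p = 0.297 with an estimated correlation). Mitochondrially encoded genes rose in 10 of 13 cases, also adjusted over the list alone (median 0.28, adjusted p = 0.0052, but adjusted p = 0.436 with an estimated correlation). Chaperone genes of the unfolded protein response rose in 15 of 20 cases and fell in 2, also adjusted over the list alone (median 0.80, adjusted p = 1.47e-04, but adjusted p = 0.141 with an estimated correlation), CALR by 2.39 ± 0.11. Cholesterol synthesis (11 higher and 3 lower of 24, also adjusted over the list alone; adjusted p = 0.0874) and fatty acid oxidation and uptake (7 and 10 of 29, also adjusted over the list alone; adjusted p = 0.418) did not pass with camera. Fry called cholesterol synthesis higher (adjusted p = 0.0328) and fatty acid oxidation and uptake lower (adjusted p = 3.78e-04).

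FOXO targets fell in 14 of 19 cases and rose in 1 (15 and 1 adjusted over the list alone; median −1.04, adjusted p = 4.78e-04, but adjusted p = 0.141 with an estimated correlation). TXNIP, an inhibitor of thioredoxin, fell from 908 ± 143 CPM to 170 ± 16.7 CPM (−2.42 ± 0.09), and PIK3IP1, an inhibitor of PI3K, changed by −3.43 ± 0.19. Targets of p53 fell in 19 of 25 cases and rose in 1 (20 and 1 adjusted over the list alone; median −0.76, adjusted p = 6.44e-05, but adjusted p = 0.173 with an estimated correlation), BTG2 by −2.99 ± 0.14. Lysosome and autophagy genes fell in 24 of 32 cases and rose in 2, also adjusted over the list alone (median −0.96, adjusted p = 1.86e-05, but adjusted p = 0.193 with an estimated correlation). SQSTM1, the autophagy receptor p62, changed by −1.52 ± 0.07. Pro-apoptotic genes fell in 7 of 10 cases and rose in 2, also adjusted over the list alone (median −0.58, adjusted p = 0.0467, but adjusted p = 0.173 with an estimated correlation). That call was lost without FGF2 early replicate 4, FL early replicate 2 or 4, or the acute library with FGF2 or FL (adjusted p = 0.0504 to 0.0523).

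Among lineage lists, MHC class II genes fell in 9 of 10 cases and rose in 1, also adjusted over the list alone (median −2.62, adjusted p = 2.96e-04, and adjusted p = 0.0428 with an estimated correlation). CD74 changed by −1.70 ± 0.07 and CIITA by −2.20 ± 0.11. Monocyte and macrophage genes fell in 15 of 28 cases and rose in 4 (16 and 4 adjusted over the list alone; median −0.84, adjusted p = 0.0092, but adjusted p = 0.399 with an estimated correlation). CSF1R, the receptor for macrophage colony-stimulating factor, changed by −3.55 ± 0.24 and CD68 by −1.38 ± 0.07. Granulocyte genes rose in 10 of 14 cases and fell in 1, also adjusted over the list alone (median 1.65, adjusted p = 0.0254, but adjusted p = 0.193 with an estimated correlation and 0.0524 without the acute library without ligand). MPO, the myeloperoxidase gene, rose from 4.92 ± 0.25 CPM to 265 ± 284 CPM (4.82 ± 0.40), and CSF3R, the receptor for granulocyte colony-stimulating factor, changed by −1.53 ± 0.15. HOX-MEIS and KMT2A fusion targets fell in 16 of 24 cases and rose in 4, also adjusted over the list alone (median −0.41, adjusted p = 0.0121, but adjusted p = 0.145 with an estimated correlation). Among these, HOXA9 changed by −0.75 ± 0.07 and FLT3 by −0.84 ± 0.08.

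The largest rises among separated genes were in PBK (5.96 ± 0.24), PRG2 (5.93 ± 1.25), MCM10 (5.91 ± 0.21), RRM2 (5.85 ± 0.25), MYBL2 (5.69 ± 0.18), CDC45 (5.63 ± 0.19), CDC6 and ZNF367 (5.30 ± 0.15). PRG2, an eosinophil granule gene, lost its call with limma-voom (adjusted p = 0.190) and against the acute library without ligand alone (0.0506). The largest falls were in HSPA7 (−4.69 ± 0.36), LSP1 (−4.54 ± 0.16), BMF, FCGR2C (−4.11 ± 0.34), FGFR3 (−3.98 ± 0.24), NRP1 (−3.79 ± 0.20), ABTB1 (−3.77 ± 0.18) and ALDH1A3 (−3.56 ± 0.31). HSPA7 and FCGR2C have near-identical copies, and their values are uncertain. In the panel PIM1 changed by −2.94 ± 0.22, CD36 by −3.21 ± 0.21 and BCL2, a survival gene, by 0.89 ± 0.09. CPT1A passed at −0.29 ± 0.10, but not without FGF2 early replicate 1 or 2 (adjusted p = 0.0639 and 0.0613) or the acute library without ligand (−0.12, 0.228). DUSP6, an ERK phosphatase, passed at 0.73 ± 0.25. Without the acute library with FGF2 its change was 1.13, and the call was lost without the acute library with FL (adjusted p = 0.0631) or without ligand (0.44, 0.112). With upper quartile scaling the median log2 fold change of all genes moved from −0.042 to −0.164, and small falls are to be read relative to that shift.

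**Figure D3:**
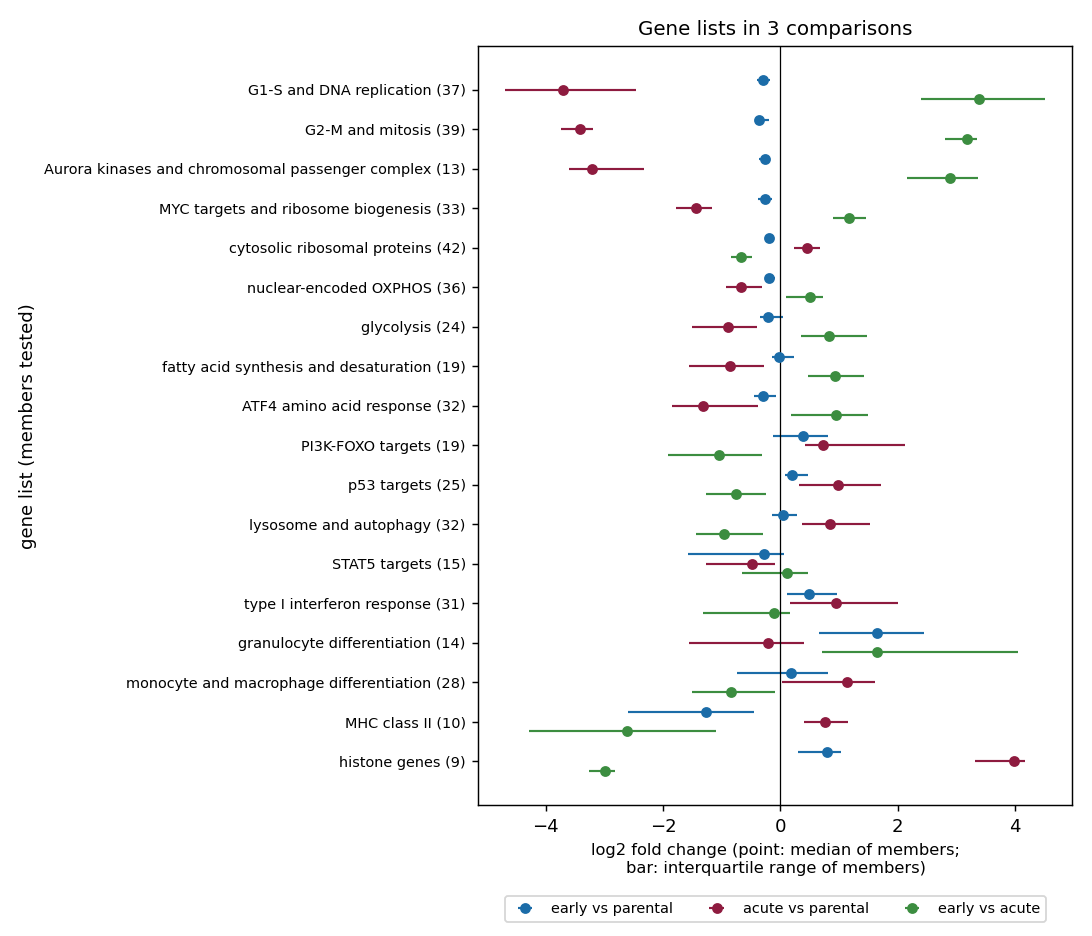
Log2 fold changes of 18 gene lists (members tested in brackets) in 3 comparisons; points are the medians of list members and bars their interquartile ranges. The G1-S list has medians of −0.30 for early vs parental, −3.70 for acute vs parental and 3.39 for early vs acute.

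Acute against parental cells gave the first response to the drug, averaged over libraries without ligand, with FGF2 and with FL. Effects of drug and ligand are thus not separated in it. Against gilteritinib alone, RAS-MAPK output genes had medians of 0.82 with FGF2 and 0.68 with FL (6 of 22 lower with each). Ribosomal protein genes had medians of 0.44 and 0.25, all from single libraries. Acute against parental is also the difference between the comparisons above. Replication and mitosis genes fell, with all 37 G1-S genes and all 39 G2-M genes lower, also adjusted over each list alone. Their medians were −3.70 and −3.42, with an adjusted p of 1.03e-23 for each list, but adjusted p = 0.0697 and adjusted p = 0.147 with an estimated correlation. CDK1 changed by −4.51 ± 0.12 and BMF by 3.93 ± 0.34. FLT3 rose from 377 ± 11.4 CPM to 716 ± 42.0 CPM (0.92 ± 0.10) and AXL by 1.37 ± 0.28 (adjusted p = 7.13e-04). In all, 5086 genes were higher and 4773 lower, 2663 and 2205 of them at least 2-fold.

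MYC targets and ribosome biogenesis genes all fell (33 of 33, also adjusted over the list alone; median −1.43, adjusted p = 1.54e-12, but adjusted p = 0.244 with an estimated correlation). ATF4 targets fell in 23 of 32 cases and rose in 3, also adjusted over the list alone (median −1.32, adjusted p = 7.57e-07, but adjusted p = 0.213 with an estimated correlation), PSAT1 by −3.62 ± 0.13. Ribosomal protein genes rose in 31 of 42 cases and fell in 1 (31 and 2 adjusted over the list alone; median 0.46, adjusted p = 1.96e-05, but adjusted p = 0.530 with an estimated correlation). Targets of p53 rose in 19 of 25 cases and fell in none, also adjusted over the list alone (median 0.98, adjusted p = 6.11e-06, but adjusted p = 0.162 with an estimated correlation). FOXO targets rose in 13 of 19 cases and fell in 1, also adjusted over the list alone (median 0.72, adjusted p = 3.46e-04, but adjusted p = 0.147 with an estimated correlation), TXNIP by 2.28 ± 0.12. Lysosome and autophagy genes rose in 25 of 32 cases and fell in 2, also adjusted over the list alone (median 0.84, adjusted p = 6.11e-06, but adjusted p = 0.185 with an estimated correlation), and monocyte genes in 13 of 28 with 3 lower, also adjusted over the list alone (1.14, 0.0206, but adjusted p = 0.454 with an estimated correlation). CSF1R rose by 3.40 ± 0.34 and CTSD, an acid protease of lysosomes, by 2.48 ± 0.19. Interferon-stimulated genes rose in 17 of 31 cases and fell in 2, also adjusted over the list alone (median 0.95, adjusted p = 0.0045, but adjusted p = 0.309 with an estimated correlation).

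STAT5 targets fell in 8 of 15 cases and rose in 1, also adjusted over the list alone (median −0.48, adjusted p = 0.0380, but adjusted p = 0.309 with an estimated correlation), CISH by −2.00 ± 0.13. That call was lost without parental replicate 3 (adjusted p = 0.0540) or the acute library without ligand (0.0804). Genes of the RAS-MAPK output list fell in 10 of 22 cases and rose in 3, also adjusted over the list alone, and the list did not pass with camera (adjusted p = 0.0509). Fry called it lower (adjusted p = 6.57e-04). The largest rises among separated genes were in CAPS (4.25 ± 0.28), H2BC12 (3.98 ± 0.31), BMF, RIMBP3C (3.81 ± 0.44, with near-identical copies) and TP53INP1 (3.69 ± 0.19). The largest falls were in PBK (−6.43 ± 0.26), MCM10 (−6.32 ± 0.22), RRM2 (−5.92 ± 0.26), CDC45 (−5.91 ± 0.20) and MYBL2 (−5.84 ± 0.19).

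The early lines were compared with each other because they grew with different ligands. Each line had 1 ligand throughout, so effects of the ligand and of the line cannot be told apart, and "with FGF2" or "with FL" names both. Granulocyte genes, lower in FGF2 early cells, had the smallest adjusted p among the lists (4.73e-05), but adjusted p = 0.202 with an estimated correlation. MPO (ENSG00000005381) stood at 39.1 ± 6.79 CPM (n = 4) with FGF2 and 492 ± 227 CPM (n = 4) with FL, a log2 fold change of −3.65 ± 0.33. LYZ, the lysozyme gene of monocytes and granulocytes, stood at 99.6 ± 28.3 CPM and 610 ± 293 CPM (−2.61 ± 0.35). EGR1, an immediate early gene, stood at 101 ± 8.03 CPM with FGF2 and 19.3 ± 4.82 CPM with FL (2.38 ± 0.33). Both lay below the parental libraries (135 to 155 CPM). FOSB, another immediate early gene, differed by 2.39 ± 0.30. AXL was higher with FGF2, at 28.2 ± 1.56 CPM against 14.3 ± 6.40 CPM (0.98 ± 0.24, adjusted p = 0.0146), but not when only these lines were fitted (adjusted p = 0.0533). In all, 630 genes were higher and 1507 lower with FGF2, 73 and 744 of them at least 2-fold.

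Granulocyte genes were lower with FGF2 in 10 of 14 cases and higher in none, also adjusted over the list alone (median −1.15, adjusted p = 4.73e-05, but adjusted p = 0.202 with an estimated correlation). EPX and PRG2, both eosinophil granule genes, differed by −5.57 ± 1.06 and −5.28 ± 0.96 and lost their calls with limma-voom (adjusted p = 0.268 and 0.0666). Monocyte genes were lower in 9 of 28 cases and higher in none (15 adjusted over the list alone; median −0.73, adjusted p = 3.70e-04, but adjusted p = 0.569 with an estimated correlation). Targets of p53 were higher in 3 of 25 cases (5 adjusted over the list alone; median 0.21, adjusted p = 3.70e-04, but adjusted p = 0.569 with an estimated correlation). Lysosome genes were lower in 7 of 32 cases and higher in 1 (8 and 1 adjusted over the list alone; median −0.14, adjusted p = 0.0112, but adjusted p = 0.673 with an estimated correlation and 0.0516 with fry). Interferon-stimulated genes were higher in 6 of 31 cases (7 adjusted over the list alone; median 0.25, adjusted p = 0.0112, but adjusted p = 0.673 with an estimated correlation, 0.0916 with fry and 0.0795 without FGF2 early replicate 2). FOXO targets were lower in 7 of 19 cases (8 adjusted over the list alone; median −0.28, adjusted p = 0.0236, but adjusted p = 0.569 with an estimated correlation and 0.0721 without FL early replicate 1). IRS2, an insulin receptor substrate, differed by −1.64 ± 0.19. Unfolded protein response genes were lower in 4 of 20 cases, also adjusted over the list alone (median −0.21, adjusted p = 0.0078, but adjusted p = 0.569 with an estimated correlation and 0.0930 without FL early replicate 4).

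Mitochondrially encoded genes were lower with FGF2 in 3 of 13 cases, also adjusted over the list alone (median −0.15, adjusted p = 0.0131, but adjusted p = 0.803 with an estimated correlation and 0.147 with fry). That call was lost without FL early replicate 1 (adjusted p = 0.0895) or 4 (0.186). The G1-S list passed with 2 genes higher and 2 lower of 37, also adjusted over the list alone (median 0.069, adjusted p = 0.0346, but adjusted p = 0.803 with an estimated correlation and 0.197 with fry). Its call was lost without FGF2 early replicate 2 or 4 or FL early replicate 1 or 2 (adjusted p = 0.0721 to 0.221), and its median was 0.11 without FGF2 early replicate 1 and 0.12 without FL early replicate 4. The RAS-MAPK output list, to which EGR1 belongs, did not pass (5 higher and 1 lower of 22, also adjusted over the list alone; adjusted p = 0.398).

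Among separated genes, others with the largest differences were higher with FGF2: ATP9A (2.13 ± 0.55), PLEKHA5 (1.53 ± 0.31) and DUSP1 (1.505 ± 0.154). The ATP9A value was 3.40 without FL early replicate 4, and its call was lost without FGF2 early replicate 3 or FL early replicate 1 or 2 (adjusted p = 0.0513 to 0.0637), with no low-count filter (0.0711) and when only these lines were fitted (0.0629). The separated genes with the largest differences in the other direction were CD93 (−5.72 ± 0.61), IGFBP2 (−5.15 ± 0.34), OBSL1 (−4.89 ± 0.50), the desaturase gene FADS2 (−4.52 ± 0.79) and HSD17B12 (−4.51 ± 0.46). FADS2 lost its call with limma-voom (adjusted p = 0.0688). It stood at 1.35 to 3.55 CPM with FGF2, and with FL at 4.61, 87.4, 119 and 24.2 CPM in replicates 1 to 4. FL early replicate 1 thus lay close to the FGF2 early flasks for this gene. CD93 stood at 2.05 ± 0.25 CPM with FGF2, and with FL at 83.6, 173, 161 and 14.6 CPM in replicates 1 to 4, so replicate 4 lay between the lines. In the panel PIM1 differed by −1.64 ± 0.28, MCL1, a survival gene, by 0.57 ± 0.10 and MEIS1, a homeobox gene, by 0.54 ± 0.10. CCND2 passed at 0.53 ± 0.14, but not without FGF2 early replicate 1 or 2 or FL early replicate 2 (adjusted p = 0.0543 to 0.0641). Without FL early replicate 4, 1214 genes were higher, and without FGF2 early replicate 1, 3 or 4 or FL early replicate 2 or 3, 303 to 353.

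**Figure D4:**
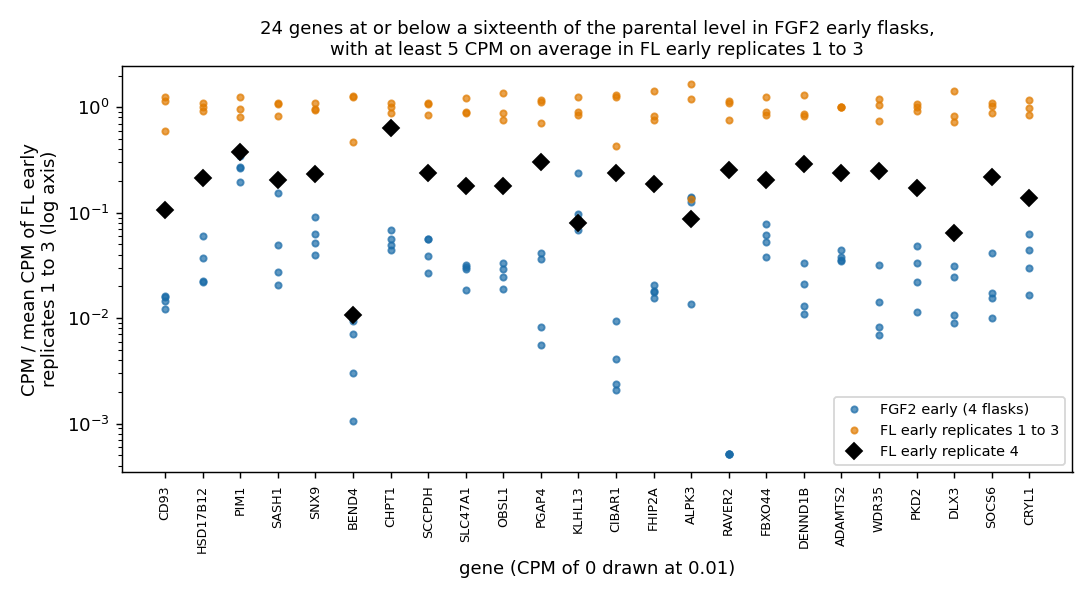
CPM in each early library divided by the mean of FL early replicates 1 to 3, on a log axis, for 24 of the 37 genes at or below a sixteenth of the parental level in FGF2 early flasks, chosen after their values were seen. The 24 had a mean of at least 5 CPM in FL early replicates 1 to 3. FL early replicate 4 (black) lies below the other FL early replicates (orange) in most of these genes and above the FGF2 early flasks (blue) in most; for CD93 it stood at 14.6 CPM.

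Each line was also set against the controls by itself. Against parental cells, 2095 genes were higher and 2698 lower in FGF2 early cells, and 1722 were higher and 1537 lower in FL early cells. Without parental replicate 1 or 2 the higher genes in FGF2 early cells numbered 1364 or 1320, and without replicate 3 they numbered 1829. For FL early cells the higher genes numbered 856, 795 and 1485 without parental replicates 1, 2 and 3, and the lower genes 795, 717 and 1196. Against acute cells, 4896 genes were higher and 5106 lower in FGF2 early cells, and 4809 were higher and 4681 lower in FL early cells. The log2 fold change of PIM1 against parental cells was −4.73 with FGF2 and −3.09 with FL, and that of PRTN3 was 1.95 and 3.14.

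Most markers of other cell types were low. A mean of at least 1 CPM in any arm was reached by none of 8 megakaryocyte markers, 1 of 11 erythroid, 1 of 8 B cell, 2 of 8 dendritic cell, 2 of 6 epithelial, 3 of 9 T and NK cell, 3 of 10 fibroblast and 3 of 7 mast cell and basophil markers. Above 10 CPM were PAX5 (74.4 CPM in FGF2 early and 41.6 CPM in acute cells), COL6A3, NKG7, EPOR, KRT18, FLT3 and GATA2. GATA2, a stem and mast cell factor, stood at 42.5 CPM in FGF2 early, 62.2 CPM in FL early, 15.96 CPM in parental and 6.58 CPM in acute cells. In the same list the tryptase genes TPSB2 and TPSAB1 stood at 2.64 and 0.554 CPM in FGF2 early and 3.17 and 1.19 CPM in FL early, against 0.058 and 0 CPM in parental cells.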

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

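The tests of a mixed culture, a mislabelled flask, carry-over between flasks, reads shared by EPX and MPO, and composition were chosen after the result was seen.

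Genes nearly silent in all FGF2 early flasks were intermediate in FL early replicate 4. Across all tested genes, log2 CPM of that flask correlated more with FGF2 early flasks (0.9747 to 0.9785) than with the other FL early flasks (0.9693 to 0.9707). FGF2 early flasks correlated with each other at 0.985 to 0.9877. Over 37 genes at or below 1/16 of their parental level with FGF2, chosen after their values were seen, the median ratio of that flask to the other FL early flasks was 0.236 (interquartile range 0.172 to 0.376), while for the other flasks it was 1.16, 1.46 and 1.14. In the labels FL early replicate 4 is flask 9, and FL early replicates 1 to 3 are flasks 10 to 12. The FGF2 early flasks are 5 to 8. What order these numbers follow is not stated. A relabelled FGF2 early flask is argued against, since 31 of the 37 genes lay above every FGF2 early flask. RNA or cells of those flasks mixed in at or after harvest are argued against only if the flask's own FL cells did not exceed FL early replicates 1 to 3. Under that assumption 10 of 14 granulocyte genes lay above the level that such a mixture would reach (MPO at 702 CPM against 134 CPM, EPX at 114 CPM against 88.4 CPM). FGF2 early cells carried over that then grew with FL stay open, since no library shows how their granulocyte genes would change. A candidate explanation, drawn from the silent genes themselves, is a mixed culture in which about 83.5% of cells (interquartile range 78.5% to 86.5% over the 24 genes with a mean of at least 5 CPM in FL early replicates 1 to 3) carry the silent state, and 7 genes high with FGF2 had a median ratio of 6.68. The same 10 granulocyte genes lie above the level of this mixture too, unless its silent-state cells differ in them from FGF2 early cells, which no library shows. Whether a subclone with that state was present when the cultures were started was not tested.

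Eosinophil granule genes were high in FL early replicates 2 to 4. EPX stood at 505, 113 and 114 CPM there, at 1.49 CPM in replicate 1 and at 2.48 to 2.86 CPM in parental libraries, and PRG2 at 1300, 314 and 262 CPM against 14.5 CPM in replicate 1. A set of 10 other eosinophil markers was scaled to total counts without TMM, unlike EPX and PRG2. Mature eosinophils in the cultures are argued against, since the median of the 10 markers in replicates 2 to 4 was 0.509 CPM and CLC, an abundant transcript of these cells, was at 0.126 CPM, while RNASE2 (442 CPM) was also expressed in parental cells (276 CPM). Some markers were higher in replicates 2 to 4 than in parental cells: PRG3 stood at 20.1, 3.44 and 2.31 CPM and at 0 CPM in parental cells, and the means of ADGRE1 and GATA1 were 3.22 and 0.621 CPM against 0.878 and 0.034 CPM. In replicate 1 PRG3 and GATA1 stood at 0.037 and 0 CPM, but ADGRE1 at 2.345 CPM, so ADGRE1 did not follow EPX and PRG2. Of the 10 markers 4 reached a mean of 1 CPM in replicates 2 to 4 and 2 in parental cells. Reads of MPO counted as its paralog EPX are argued against, since the ratio of EPX to MPO differed 114-fold between FL early flasks (0.00865 to 0.984). A start of an eosinophil granule programme in the leukaemia cells may account for these values, as a hypothesis that was not tested.

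Ribosomal protein transcripts took a larger share of counts in acute libraries (16.3% to 19.7%, against 10.8% to 13.0% elsewhere). Other genes of like length did not rise as a group. The median log2 fold change against parental cells was −0.33 for 100 such genes (95% bootstrap interval −0.67 to −0.17) and 0.46 for the ribosomal protein genes. Median expression was 9.41 log2 CPM for the 100 genes and 10.78 log2 CPM for the ribosomal protein genes. This argues against a bias towards short transcripts only if the 100 genes did not fall for other reasons, which was not tested. Scaling without ribosomal protein and mitochondrial genes left the median of the ribosomal protein genes at 0.42. This does not decide whether a fall of other abundant transcripts alone accounts for the share, since those transcripts still helped to set that scaling. A lower amount of RNA per cell could not be examined, as no added control RNA is stated.

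Single libraries far from the other libraries of their arm were found in 10 of 146 groups of values examined, and chance gives about 1 in 20. With FGF2 these were EVPL at 35.4 CPM in replicate 4 (others 15.5 to 17.1), CCR2 at 11.8 CPM in replicate 1 (4.55 to 5.07), CDC6 at 76.2 CPM in replicate 3 (78.3 to 78.5) and H2BC12 at 16.3 CPM in replicate 3 (8.06 to 9.20). In FL early replicate 1 they were CDKN1A at 150.2 CPM (others 326 to 361), BMF at 39.9 CPM (15.6 to 17.4) and the ribosomal protein share at 13.0% (11.2% to 11.5%). In FL early replicate 4 they were MEIS1 at 47.4 CPM (34.9 to 36.7), ATP9A at 28.8 CPM (2.39 to 5.54) and PLEKHA5 at 15.2 CPM (3.86 to 5.49).

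The change against parental cells differed between the early lines, by the test of FGF2 early against FL early, in 12 of 40 named genes. The log2 difference was positive for AXL (0.98), CCND2 (0.53), MCL1 (0.57) and MEIS1 (0.54). It was negative for PIM1 (−1.64), PRTN3 (−1.19), CCNA1 (−1.76), CEBPD (−1.07), HOMER3 (−0.86), ELANE (−0.86), IGFBP2 (−5.15) and EPHB3 (−1.11). By camera 9 lists differed, with medians of −0.28 for FOXO targets, 0.0685 for G1-S, 0.21 for p53 targets, −0.15 for mitochondrially encoded genes, −0.21 for the unfolded protein response, −0.14 for lysosome, −0.73 for monocyte, −1.15 for granulocyte and 0.25 for interferon genes. None of these lists passed with an estimated correlation.

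Other splits of the libraries into groups of the same sizes were fitted on the libraries of each comparison alone. In each comparison the real split was the only 1 with as many genes past the threshold. For early vs parental it gave 3692 genes against at most 708 in the others of 100 splits drawn, and for early vs acute 9268 against 98. With all 35 splits counted, the real and the highest other were 1464 and 1 for FGF2 early vs FL early, 6757 and 2 for FGF2 early vs parental and 2393 and 80 for FL early vs parental. Against acute cells they were 10005 and 0 for FGF2 early and 8297 and 62 for FL early. In these 7 comparisons the real split was thus a share under 0.05 of the splits fitted. Other splits mix libraries of different arms, which widens the spread within groups and lowers their counts. They also take the libraries of an arm as independent, which nothing states, so chance is not excluded by them. Acute vs parental has 10 splits, too few for a share under 0.05, with 9830 genes for the real split and 0 for the highest other.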

How the results depend on the processing

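Leaving out FL early replicates 1 and 4 together, using only named identifiers, and scaling without ribosomal protein and mitochondrial genes were chosen after the data were seen. Each result was recomputed under up to 31 alternatives, 14 of them leaving out 1 library. Of 622 gene results, 503 kept their direction and their side of the threshold under each alternative that gave a value, and 11 changed sign in at least 1. Of 62 list results, 4 kept their call under each alternative, and of 24 counts, 5 stayed within 1.5 times under each. Over single recomputed values, for lists 1120 kept the call and 93 lost it, and for counts 467 stayed within 1.5 times and 43 moved. Where no cause is named below, the cause was not tested.

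Requiring a 2-fold change left, by construction, 389 higher and 683 lower genes for early vs parental, 1888 and 2526 for early vs acute, 2663 and 2205 for acute vs parental, and 73 and 744 for FGF2 early vs FL early. With an estimated correlation 1 list was higher and 1 lower for early vs parental, 1 and 1 for early vs acute, and 0 and 0 for acute vs parental and for FGF2 early vs FL early. Fry called 6 lists higher for early vs parental, 18 lower for early vs acute and 18 higher for acute vs parental. For FGF2 early vs FL early DESeq2 called 995 genes higher, and without FL early replicates 1 and 4 the number was 1299. Without those replicates 5 lists were higher for early vs parental. Upper quartile scaling moved the median log2 fold change of all genes to −0.164 for early vs acute (4292 higher, 6208 lower) and 0.180 for acute vs parental (5772 and 4232).

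Leaving out 1 library at a time gave, for early vs parental, 1136 to 2393 genes higher and 1549 to 2944 lower. The lowest counts came without parental replicate 2 and the highest without the acute library without ligand, while without parental replicate 3 they were 1771 and 1980. For FGF2 early vs parental 1320 to 2435 were higher. For FL early vs parental 795 to 1963 were higher and 717 to 1980 lower. For FGF2 early vs FL early 303 to 1214 genes and 1 to 3 lists were higher.

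Replicate numbers as a block gave 179 higher and 569 lower genes for FGF2 early vs FL early and 976 and 829 for FL early vs parental. Libraries that share a number were no more alike (correlations of residuals across genes −0.0939 to 0.0658 in 10 pairs) than others (−0.126 to 0.0961 in 30 pairs), so the block was not used. With the block, for FGF2 early vs FL early, calls were lost for AXL (adjusted p = 0.0521), CCND2 (0.0831), ATP9A (0.0628), CCNA1 (0.0561), EPX (0.0644), PRG2 (0.0677) and FADS2 (0.0539), and for early vs parental for BCL2L11 (0.0943). With the block the change for early vs parental was 0.0151 for CCND1 and 9.51e-04 for MYC.

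Genes that changed sign had not passed the test before. For early vs acute AXL was at −0.0684 with upper quartile scaling, −0.0100 with limma-voom, −0.0154 with ligand-matched acute libraries, −0.0178 with only the acute libraries given a ligand, −0.0419 to 0.149 without 1 library, and −0.242 without FL early replicates 1 and 4, the only reversed value that passed (adjusted p = 0.0315). For early vs parental CCND1 was at 0.142 without those replicates, and without 1 library CCND1 ran from −0.241 to 0.0316, MYC from −0.0614 to 0.0411 and SCD from −0.186 to 0.0378. For acute vs parental DUSP6 was at 0.0798 with only the libraries given a ligand and at −0.614 to 0.0798 without 1 library. For FGF2 early vs FL early, without FL early replicates 1 and 4, AURKB was at −0.0821, DUSP6 at −0.0714 and CDKN1A at −0.143. Without 1 library the ranges were −0.0134 to 0.149 for AURKB, −0.0412 to 0.263 for DUSP6, −0.181 to 0.146 for CDKN1A, −0.0429 to 0.289 for CD36, −0.117 to 0.0120 for FGFR1 and −0.180 to 0.0054 for MKI67. In simulated data for early vs parental 34.3% of changes of 1.5-fold were recovered. Far fewer genes changed there than were called in the data, so how often such changes were missed in the data is not known.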

Other observations

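The comparison between single acute libraries, which has no replicates and no test, was chosen after the data were seen, on gene lists fixed before. Ligand given during acute treatment went with higher levels of most ERK output genes and of MYC in these libraries. With FGF2 or FL, compared with gilteritinib alone, the 22 RAS-MAPK output genes had a median log2 difference of 0.82 and 0.68, each at percentile 100 of 10000 random lists matched on expression, though 6 of the 22 were lower with each ligand. MYC stood at 89.9 CPM with gilteritinib alone, 357 CPM with FGF2 and 275 CPM with FL, and DUSP6, an ERK phosphatase, at 31.0, 83.7 and 56.4 CPM. FOSL1, an ERK-induced AP-1 factor, stood at 2.03, 5.91 and 6.54 CPM, while immediate early genes were lower with both ligands, EGR1 at 47.3, 14.2 and 12.9 CPM and FOS at 210, 138 and 134 CPM, and EGR2, EGR3, FOSB and DUSP1 likewise. MYC targets and ribosome biogenesis genes had medians of 0.71 and 0.48, each at percentile 100, and ribosomal protein genes 0.44 (percentile 100) and 0.25 (99.9).

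Most cholesterol synthesis genes (21 of 24) and interferon genes (23 of 31) were lower in each of the libraries with ligand. The medians of cholesterol synthesis genes were −0.60 with FGF2 and −0.36 with FL, and those of interferon-stimulated genes −0.41 and −0.42, each at percentile 0. SCD, a desaturase, stood at 149 CPM with gilteritinib alone, 102.8 CPM with FGF2 and 105 CPM with FL, while the medians of its list, fatty acid synthesis, were 0.02 and −0.08 (percentiles 21.96 and 5.42). G2-M genes had medians of −0.09 (percentile 0.8) and −0.20 (0). Lysosome genes had medians of −0.29 (percentile 0) and −0.16 (0.46), and glycolysis genes 0.40 and 0.26 (percentiles 99.97 and 99.71). These numbers compare libraries, not conditions.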
